A study of Mus musculus with 9 samples.

How the data were processed

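Large intestine RNA from mice with a control hairpin (3 samples), the hairpin DHX9-1271 (3 samples) and the hairpin DHX9-837 (3 samples) was labelled with biotin and hybridised to Affymetrix Mouse Gene 2.0 ST arrays, per the labels' protocols. Groups and replicate numbers came from the sample titles. The deposited values are log2 expression levels, 24973 probe sets by 9 arrays, made by the authors with RMA, oligo 1.30.0 and R 3.1.1, per the submitters' processing notes. RMA as a method corrects background, normalizes by quantiles and summarises the probes of a probe set by median polish; the options used are not given in the sources used here. The probe set definition and genome build are not given in the sources used here. A quantile step forces a common distribution on the arrays, so a shift of most transcripts in one direction would not be seen. Median polish can leave identical values, and 45.3% of tested genes had the same value in 2 or more arrays. No arrays had identical columns.

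Probe sets were named through the platform's probe table. It gave exactly 1 symbol for 24015 probe sets, several for 0, and did not list 958. Of the listed Entrez Gene numbers, 23922 were found in a reference gene table, and 0 symbols changed on updating. The brightest probe set was kept for each of 24011 symbols, which dropped 4. Genes with a mean log2 level over the 9 arrays under the 30th percentile (5.28) were left out, which left 16808 genes and removed 7203. Because the probe set definition is not given, genes with near-identical copies, antigen receptor segments above all, are uncertain. For arrays there is no read depth, and the number of arrays limits the precision.

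Tests used limma 3.58.1 in R 4.3.3, with a group-means model over all 9 arrays, 4 contrasts, empirical Bayes moderation without trend (6 residual degrees of freedom, 2.84 prior degrees of freedom) and two-sided p-values adjusted by Benjamini and Hochberg over the genes tested. A gene was called at an adjusted p under 0.05 with no fold limit. The contrast of both hairpins with control is the mean of the hairpin group means minus the control mean. The median residual SD was 0.0913 on the log2 scale. Dhx9 was also tested by exact two-sided permutation of the arrays compared. Design, gene lists, naming rule and most alternatives were fixed before the data were examined.

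Named genes were the 12 largest rises and 12 largest falls (8 and 8 between hairpins) among called genes whose arrays all lay beyond those of the reference group, besides Dhx9. Predicted genes, small RNAs, antigen receptor segments, olfactory and vomeronasal receptors and clone names were counted but not named. From each list up to 4 members of smallest p were named. The 30 lists held 605 genes, 36 of which had no probe set named here; 29 lists had at least 5 tested genes and were tested. Camera compared each list with the other genes (preset inter-gene correlation 0.01), with an estimated correlation and fry beside it. Fry tests whether a list's genes move, on balance, one way, without comparing them with other genes, and it called 10, 11, 12 and 3 lists for DHX9-1271, DHX9-837, both hairpins and the difference. List counts "adjusted over the list alone" use Benjamini and Hochberg within the list.

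The method was tested on simulated data with 200 of 16808 genes changed. For DHX9-1271 vs control it recovered 85% of 1.5-fold and 98% of 2-fold changes with 5.67% false calls, and for DHX9-837 90%, 100% and 5%. For both hairpins it recovered 97% and 100% with 7.94% false calls, and for the difference 86% and 99% with 3.65%. A simulated list shift of 0.3 was called with 0 other lists. The simulated genes varied independently of each other. Real lists had estimated correlations such as 0.73 (B and plasma cells) and 0.52 (cell cycle). The simulation therefore cannot show how often correlated lists are called falsely, and its shares of false calls hold for independent genes. Shared controls were simulated 100 times. Alternatives covered the level filter, probe sets per gene, all probe sets as features, centring, cyclic loess, trend and robust moderation, array weights, the arrays compared alone, the replicate number as a block, a 1.5-fold limit and leaving out each array. Genes with identical values in 2 or more arrays were left out, and the B cell list mean was used as a covariate for the cell cycle list, as alternatives added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.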

Results

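Total RNA from the large intestine of C57BL/6 mice was profiled on 9 oligonucleotide arrays that measure mouse transcripts over the length of each gene. The mice carried a short hairpin RNA switched on by doxycycline together with rtTA, the doxycycline-dependent activator. The hairpin was directed either against firefly luciferase, which mice do not have (control), or against the RNA and DNA helicase gene Dhx9, with the lines named DHX9-1271 and DHX9-837. Each of the 3 groups held 3 arrays. All mice had received doxycycline at 1 mg/ml with 5% sucrose in the drinking water for 14 days from 4 weeks of age. Median log2 levels of the 9 arrays lay between 6.25 and 6.28. The number of arrays limits the precision of each value. The labels do not say that the replicates came from separate animals, so p-values measure the spread between these samples. Pairs of arrays of 1 group correlated across genes at 0.979 to 0.995, and pairs from different groups at 0.959 to 0.988.

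Dhx9 was lower in every array of the knockdown groups than in every control array. Its log2 level was 9.24 ± 0.072 in control, 8.22 ± 0.045 in DHX9-1271 and 8.20 ± 0.017 in DHX9-837 (SD, n = 3 arrays each). Against control, DHX9-1271 left 49.6% of the Dhx9 signal (log2 fold -1.01, SE 0.051, adjusted p = 4.91e-05) and DHX9-837 left 48.8% (log2 fold -1.03, SE 0.051, adjusted p = 2.05e-05). The hairpins differed from each other by -0.02 on the log2 scale (95% interval -0.14 to 0.094, adjusted p = 0.908). An exact two-sided permutation test gave p = 0.1 for each hairpin against control, the smallest that 3 arrays against 3 allow, and p = 0.0119 for the knockdown arrays together. Of the 16 DExH-box helicases tested in both hairpins against control, Dhx9 fell, Dhx15 rose (log2 fold 0.17, adjusted p = 0.0394) and 14 were not called. The counts were the same adjusted over the list alone, and the list as a whole was not called (median -0.0017, adjusted p = 0.977).

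**Figure D1:**
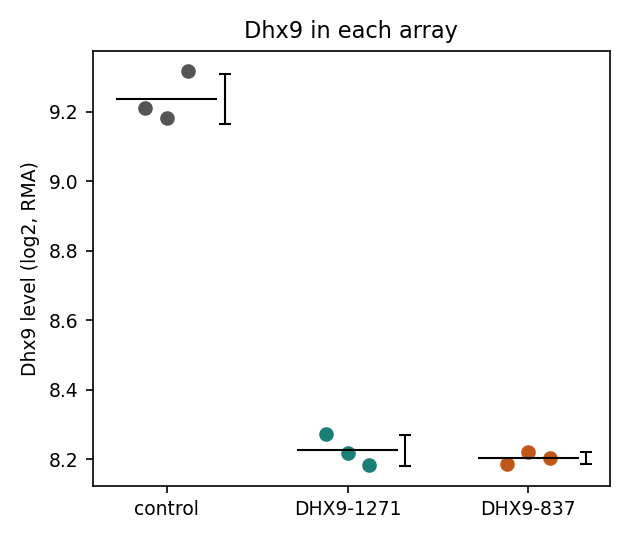
Dhx9 level (log2, RMA) in each of the 9 arrays by group, with points for arrays, horizontal lines for group means and bars for 1 SD. The control arrays lie between 9.18 and 9.32, and the 6 knockdown arrays between 8.18 and 8.27.

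The series compares large intestine with and without reduced DHX9, and the contrast of both hairpins with control addresses that question directly. S100g, which encodes the calcium-binding protein calbindin-D9k, fell by 3.53 on the log2 scale (SE 0.21, adjusted p = 7.23e-05), and Trpv6, an apical calcium channel, fell by 2.79 (SE 0.24, adjusted p = 0.000383). The mucosal pentraxin gene Mptx1 fell by 2.84 (SE 0.44, adjusted p = 0.0046), and the acute-phase gene Saa1 fell by 2.14 (SE 0.10, adjusted p = 1.72e-05). The carboxylesterase gene Ces2a fell by 2.15, and the gasdermin genes Gsdmc2 (-2.14) and Gsdmc3 (-1.88) fell too. Sycn, which encodes a zymogen granule protein, Cyp4f15, the complex I subunit gene Ndufb2, Apol10a and Pck1, which encodes an enzyme of gluconeogenesis, completed the 12 largest falls, with log2 folds from -2.25 (Sycn) to -1.15 (Pck1). Mptx1 and Cyp4f15 in DHX9-837 (means 5.03 and 4.77) and Slc7a11 in control lay under the level filter of 5.28, so the sizes of their folds are uncertain.

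Among the largest rises, the aldo-keto reductase gene Akr1b8 had a log2 fold of 1.62 (SE 0.16, adjusted p = 0.00069) and the clock repressor gene Nr1d1 one of 1.47 (SE 0.25, adjusted p = 0.00714). Asns, which encodes asparagine synthetase, rose by 1.43 (SE 0.11), the lipase-family gene Pnpla1 by 1.47 (SE 0.054) and the tight-junction claudin gene Cldn8 by 1.38 (SE 0.11). Sprr1a, the water channel gene Aqp4, Plet1, the phospholipid acyltransferase gene Lpcat4, the cystine transporter gene Slc7a11, the EGF receptor ligand gene Ereg and Ms4a12 rose by 1.05 to 1.27. Over all 16808 genes tested, 1367 rose and 896 fell at an adjusted p under 0.05, of which 40 and 21 changed at least 2-fold (17 and 18 outside antigen receptor genes). Antigen receptor genes made up 51 of the rises and 8 of the falls (250 tested); their segments are near-identical copies, so their single values are uncertain. Without control replicate 1 the counts were 779 and 584, and without DHX9-1271 replicate 3 they were 876 and 585. With each array centred on its median, 1111 rose and 1180 fell.

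Of 29 gene lists fixed beforehand, 11 were called against the other genes by camera with a preset inter-gene correlation. With an estimated correlation 0 of the 29 were called in this comparison or in any of the 3 others, so the camera calls rest on the preset value. Fry, which does not compare a list with other genes, called 12 lists in this comparison, not all of them the same ones. The cell cycle list had the smallest camera p. Of its 32 tested members 21 rose, 0 fell and 11 were not called (26 rose adjusted over the list alone). The spindle factor gene Tpx2 (log2 fold 0.49, SE 0.043), the proliferation marker Mki67 (0.59, SE 0.075) and the mitotic genes Ccnb2 (0.66, SE 0.097) and Ube2c (0.69, SE 0.11) were its members of smallest p. The list had a median log2 fold of 0.33 (adjusted p = 4.7e-12, or adjusted p = 0.362 with an estimated correlation). In ribosome biogenesis, 10 of 25 genes rose and 0 fell (14 rose adjusted over the list alone), among them Nop2 (0.44), Gnl3 (0.55) and the nucleolin gene Ncl (0.37). Its median was 0.15 (adjusted p = 4.82e-07, or adjusted p = 0.254 with an estimated correlation). Of the 21 Wnt target and crypt stem cell genes 5 rose and 1 fell, with the same counts adjusted over the list alone. Cd44 (0.51), Slc12a2 (0.28) and Myc (0.50) rose and Prom1 (-0.36) fell. That list had a median of 0.11 (adjusted p = 0.0183, or adjusted p = 0.362 with an estimated correlation), and its call ended without control replicate 3 (adjusted p = 0.0585) and without tied genes, those that have identical values in 2 or more arrays (adjusted p = 0.106, with a median of 0.149).

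Lists that mark other cells of the gut wall were called upward by camera with the preset correlation in the same contrast. Fry also called macrophages and granulocytes (adjusted p = 0.00284), fibroblasts and matrix (adjusted p = 0.011) and endothelium (adjusted p = 0.00185). It did not call B and plasma cells (adjusted p = 0.0641) or MHC class II (adjusted p = 0.0917). B and plasma cell genes had 7 of 19 members up and 0 down (13 up adjusted over the list alone) and a median of 0.43 (adjusted p = 1.71e-05, or adjusted p = 0.536 with an estimated correlation). Pax5 (0.45, SE 0.073), Cd22 (0.63, SE 0.12) and Ighm (0.68, SE 0.14) were among them. The list's mean per array was 6.84 to 6.95 in controls, 7.06 to 7.55 in DHX9-1271 and 7.13 to 7.46 in DHX9-837. Of 10 MHC class II genes only H2-DMb2 rose (0.79, adjusted p = 0.0363), and 7 rose adjusted over the list alone. The median was 0.23 (adjusted p = 0.0113, or adjusted p = 0.575 with an estimated correlation), and the call ended with the filter at the median gene (adjusted p = 0.0663). Of 17 macrophage and granulocyte genes, 5 rose and 1 fell, with the same counts adjusted over the list alone. The receptor gene Csf1r (0.48, SE 0.046) and the complement genes C1qc (0.50) and C1qb (0.40) rose, whereas Cd14 fell (-0.43). The macrophage list had a median of 0.12 (adjusted p = 0.00648, or adjusted p = 0.262 with an estimated correlation), or 0.0651 without control replicate 3 (adjusted p = 0.0459) and 0.383 without tied genes (adjusted p = 0.0202). Fibroblast and matrix genes had 6 of 19 up, Fbln1 (0.35), Postn (0.36) and Dcn (0.38) included, and 0 down (13 up adjusted over the list alone). Their median was 0.19 (adjusted p = 4.3e-06, or adjusted p = 0.362 with an estimated correlation). Endothelial genes had 7 of 18 up, with Emcn (0.35) and Eng (0.30), and 0 down (8 up adjusted over the list alone). The endothelial median was 0.13 (adjusted p = 0.000117, or adjusted p = 0.254 with an estimated correlation).

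Lists called downward in the pooled contrast were absorptive colonocytes, immediate early and heat shock genes, and the circadian clock. Of 24 absorptive colonocyte genes 7 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.11 (adjusted p = 0.00142, or adjusted p = 0.254 with an estimated correlation). Slc37a2 (-0.85, SE 0.069), the chloride-bicarbonate exchanger gene Slc26a3 (-0.45, SE 0.047), Mall (-0.42) and the guanylin gene Guca2a (-0.28) fell. Among immediate early and heat shock genes 5 of 23 fell and 2 rose (7 and 2 adjusted over the list alone). Fosb (-0.44), Nr4a1 (-0.85) and Klf4 (-0.27) fell and Fosl1 (0.39) rose. This list had a median of -0.084 (adjusted p = 0.00648, or adjusted p = 0.395 with an estimated correlation), or -0.129 without control replicate 1 and -0.147 without tied genes. With DHX9-837 alone it was not called (median -0.084, adjusted p = 0.327). Of 16 clock genes 9 fell and 4 rose (10 and 4 adjusted over the list alone). Per2 (-1.03, SE 0.064), Per3 (-0.79, SE 0.092) and Cry2 (-0.50, SE 0.074), which encode clock repressors, fell, and the activator gene Npas2 (0.45, SE 0.056) rose. The clock list had a median of -0.32 (adjusted p = 0.00695, or adjusted p = 0.254 with an estimated correlation). Its call ended without genes that have identical values in 2 or more arrays, an alternative added after the data were seen (adjusted p = 0.639), while the median there was -0.305.

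Camera with the preset correlation did not call the other lists in this contrast. Among them, fry called unfolded protein and integrated stress response (adjusted p = 0.00185) and p53 targets (adjusted p = 0.011) upward. It called NF-kB and epithelial inflammation downward (adjusted p = 0.015). Unfolded protein and integrated stress response genes had 7 of 23 up and 1 down (8 and 1 adjusted over the list alone). Shmt2 (0.75, SE 0.047), Asns, Mthfd2 (0.99, SE 0.11) and Psat1 (0.71, SE 0.083), which encode enzymes of amino acid and one-carbon synthesis, rose. The list had a median of 0.039 (adjusted p = 0.065) and was called without DHX9-837 replicate 1 (median 0.0367, adjusted p = 0.0416) and with no level filter (adjusted p = 0.011). Of 22 p53 targets 4 rose and 2 fell, with Ccng1 (0.42), Plk2 (0.40), Rps27l (0.21) and Cdkn1a (0.23) up (median 0.082, adjusted p = 0.368). Saa1 and Saa3 (-1.09) fell and Duoxa2 (0.34) and Birc3 (0.20) rose among 19 genes of NF-kB and epithelial inflammation (median -0.044, adjusted p = 0.574). In PPAR and fatty acid oxidation 6 of 19 rose and 2 fell, with Pdk4 (0.90) and Angptl4 (0.97) up and Slc25a20 (-0.66) and Ppara (-0.37) down (median 0.029, adjusted p = 0.574). Among 20 goblet cell genes Creb3l1 (0.35), Agr2 (0.52) and Ern2 (0.25) rose and Tff3 (-0.28) fell (median 0.093, adjusted p = 0.173). That list was called without control replicate 2 (median 0.165, adjusted p = 0.0056) and with no level filter (adjusted p = 0.0461), and its median was 0.0277 without control replicate 1. Of 19 enteroendocrine genes Gcg rose (0.54) and Chga fell (-0.33; list median -0.014, adjusted p = 0.977). General epithelium had Krt18 (0.66), Krt19 (0.24) and Tspan8 (0.18) up and Cldn3 (-0.29) down of 19 (median 0.0064, adjusted p = 0.648). Of 17 T and NK cell genes Cd4 rose (0.65; list median -0.12, adjusted p = 0.148), and the list was called downward without control replicate 2 (median -0.192, adjusted p = 0.0437) and without DHX9-837 replicate 3 (median -0.123, adjusted p = 0.0359).

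In the interferon response list Bst2 (0.40) and Eif2ak2 (0.24) rose and Gbp2 (-0.48) fell of 29, with a median of -0.0034 (adjusted p = 0.977). Smooth muscle had 0 of 20 called by limma (median -0.019, adjusted p = 0.574, but called without control replicate 1 with a median of -0.0719 and adjusted p = 0.0434), and tuft cells 0 of 15 (median 0.033, adjusted p = 0.977). Posterior Hox genes had 0 of 10 called (median -0.029, adjusted p = 0.933) and pancreas 0 of 7 (median -0.020, adjusted p = 0.933). Of 15 enteric neuron and glia genes Vip rose (0.25; list median 0.031, adjusted p = 0.682). Of 17 cholesterol synthesis genes Pmvk fell (-0.37; list median -0.012, adjusted p = 0.644). Of 11 adipocyte genes Lpl rose (0.58) and Pck1 fell (list median 0.027, adjusted p = 0.977). The adipocyte list moved in opposite directions with each hairpin alone. Its median was -0.179 with DHX9-1271 (adjusted p = 0.0303) and 0.408 with DHX9-837, where it was not called (adjusted p = 0.0561). Of 18 small intestine genes Alpi fell (-0.66; list median 0.0018, adjusted p = 0.574). The small intestine list's mean per array ran from 6.67 to 9.24 and overlapped between all groups. Adjusted over the list alone, 5 p53 targets rose and 3 fell, 5 goblet cell genes rose and 1 fell, 5 general epithelium genes rose and 1 fell, and 6 PPAR genes rose and 3 fell. Neither Vip nor Pmvk was called by that adjustment, and the other counts of lists not called were the same. Median, mean and camera direction did not share a sign for small intestine, adipocytes, interferon response, enteroendocrine cells and DExH-box helicases. Erythroid genes were not tested as a list, since 2 of 11 passed the level filter.

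**Figure D2:**
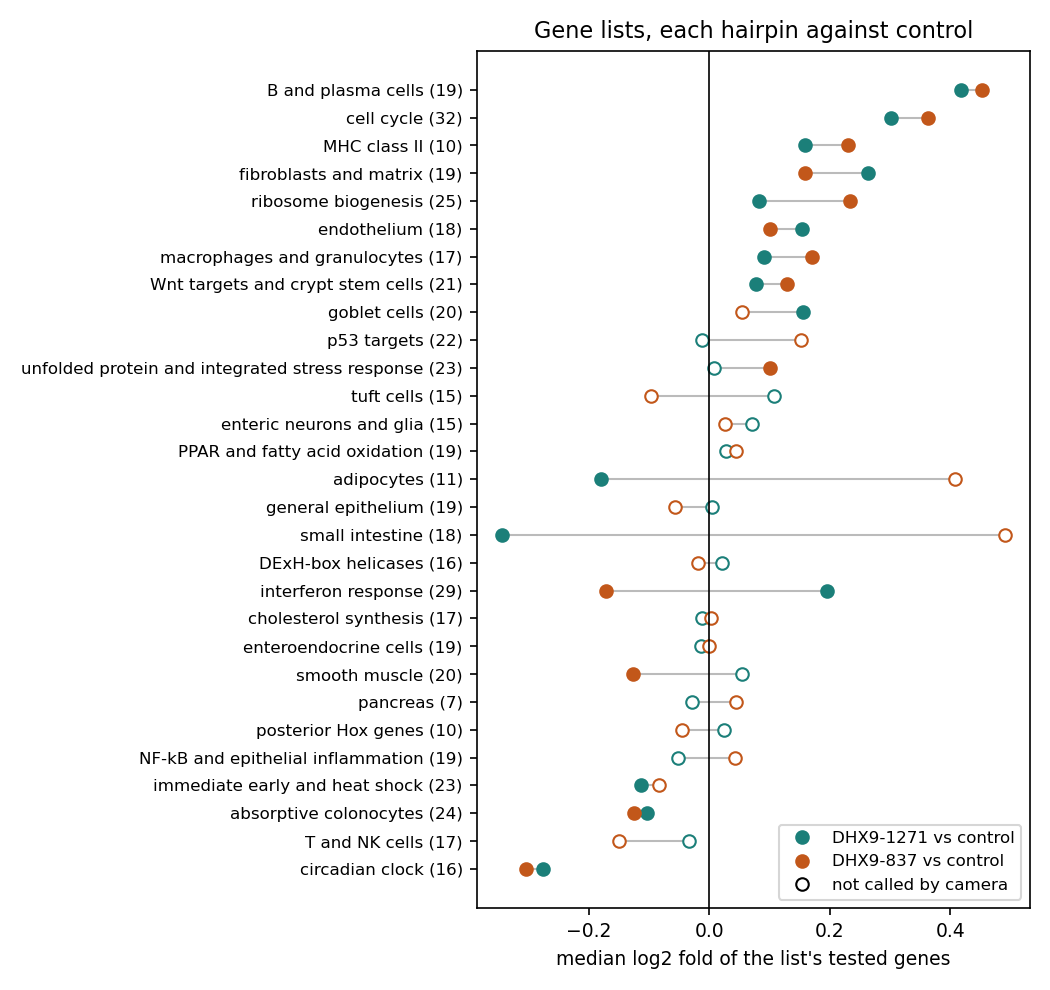
Median log2 fold of each gene list against control for DHX9-1271 (green) and DHX9-837 (orange), with the number of tested genes in brackets and filled points where camera with the preset correlation called the list. B and plasma cell and cell cycle genes have positive medians with both hairpins, clock genes negative ones, and the interferon response list has medians of 0.20 and -0.17.

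DHX9-1271 alone against control gave 475 genes up and 266 down. Nr1d1 rose most (log2 fold 2.12, SE 0.29, adjusted p = 0.00905), followed by Pnpla1 (1.28), Asns (1.21), Akr1b8 (1.21), the transcription factor gene Klf12 (1.09), Cldn8 (1.08) and Pdk4 (1.07). Glycam1, Sprr1a, St3gal3, Pigl and Ly6g6c rose by 0.88 to 1.00. The control mean of Klf12 (5.23) lay under the level filter, so the size of its fold is uncertain. S100g fell by 2.79 (SE 0.25, adjusted p = 0.0013), Trpv6 by 2.12 (SE 0.28) and Ces2a by 2.00 (SE 0.13). Sycn (-1.89) and Saa1 (-1.59) fell as well. Gsdmc2 (-1.39), Ndufb2 (-1.37), Per2 (-1.27), Gsdmc3 (-1.27), the matricellular genes Ccn1 (-1.10) and Ccn2 (-1.06), and the immediate early gene Nr4a1 (-1.03) were also lower. Of the 25 genes named here, 9 lost their call in at least 1 fit that left out an array. The counts fell to 217 up and 124 down without control replicate 1, to 189 and 104 without DHX9-1271 replicate 1, to 131 and 73 without replicate 2 and to 77 and 51 without replicate 3; without control replicate 3, 138 fell. With arrays centred on their median 388 rose and 343 fell, and with cyclic loess 424 and 364.

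Camera called 15 lists with DHX9-1271. Cell cycle genes had 12 of 32 up and 0 down (23 up adjusted over the list alone, median 0.30, adjusted p = 8.21e-11, or adjusted p = 0.367 with an estimated correlation). Fibroblast and matrix genes had 2 of 19 up (13 adjusted over the list alone, median 0.26, adjusted p = 2.52e-07, or adjusted p = 0.36 with an estimated correlation). Endothelium had 5 of 18 up (8 adjusted over the list alone, median 0.15, or 0.264 without tied genes, adjusted p = 5.49e-06, or adjusted p = 0.207 with an estimated correlation). Interferon response genes had 4 of 29 up and 0 down (7 up adjusted over the list alone), with Stat2 (0.39), Irf7 (0.40), Eif2ak2 (0.33) and Rsad2 (0.74). Their median was 0.20 (adjusted p = 0.000764, or adjusted p = 0.601 with an estimated correlation), and the call ended without control replicate 2 (median 0.11, adjusted p = 0.0705). B and plasma cells had 2 of 19 up (10 adjusted over the list alone, median 0.42, adjusted p = 0.000175, or adjusted p = 0.601 with an estimated correlation). Ribosome biogenesis had 4 of 25 up (6 adjusted over the list alone, median 0.083, or 0.0552 with arrays centred, adjusted p = 0.00191, or adjusted p = 0.367 with an estimated correlation). Goblet cells had 3 of 20 up (3 up and 1 down adjusted over the list alone, median 0.16, adjusted p = 0.00577, or adjusted p = 0.601 with an estimated correlation). Macrophages had 2 of 17 up (3 up and 1 down adjusted over the list alone, median 0.091, or 0.268 without tied genes and 0.146 with the filter at the median gene, adjusted p = 0.0281, or adjusted p = 0.367 with an estimated correlation). MHC class II had 0 of 10 called by limma (0 adjusted over the list alone, median 0.16, adjusted p = 0.0186, or adjusted p = 0.601 with an estimated correlation). Wnt targets and crypt genes had 2 of 21 up (3 up and 1 down adjusted over the list alone, median 0.078, or 0.0501 with arrays centred, adjusted p = 0.0287, or adjusted p = 0.367 with an estimated correlation).

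The 5 lists called downward with DHX9-1271 began with immediate early and heat shock genes, 3 of 23 down (7 adjusted over the list alone), with Fosb (-0.55), Nr4a1 and Hspa1b (-0.85). That list had a median of -0.11 (adjusted p = 4.66e-06, or adjusted p = 0.207 with an estimated correlation), or -0.179 without control replicate 2 and -0.232 without tied genes. Absorptive colonocytes had 3 of 24 down (6 adjusted over the list alone, median -0.10, adjusted p = 0.000286, or adjusted p = 0.207 with an estimated correlation). Clock genes had 4 of 16 down and 2 up (8 and 4 adjusted over the list alone, median -0.28, adjusted p = 0.00401, or adjusted p = 0.207 with an estimated correlation). Small intestine genes had 1 of 18 down, Alpi (-0.70), and the same count adjusted over the list alone, with list means per array of 6.90, 8.50 and 7.83 in control and 7.54, 6.67 and 7.40 in DHX9-1271. The median was -0.34 (adjusted p = 0.00562, or adjusted p = 0.601 with an estimated correlation), and the call ended without control replicate 2 (median -0.147, adjusted p = 0.165) and without DHX9-1271 replicate 2 (median -0.192, adjusted p = 0.0643). Without control replicate 1 that median was -0.536, and without tied genes -0.524. Adipocyte genes had 2 of 11 down, Pck1 (-0.74) and Car3 (-1.01), and 4 down and 1 up adjusted over the list alone. Their median was -0.18 (adjusted p = 0.0303, or adjusted p = 0.601 with an estimated correlation), and the call ended without control replicate 2 (median -0.0324, adjusted p = 0.307) and without DHX9-1271 replicate 2 (median -0.0785, adjusted p = 0.104). Leaving out control replicate 1 ended the goblet call (median 0.0592, adjusted p = 0.206), and control replicate 3 the macrophage (adjusted p = 0.129) and Wnt (adjusted p = 0.102) calls. MHC class II lost its call without DHX9-1271 replicate 2 (adjusted p = 0.0612). Leaving out genes with identical values in 2 or more arrays ended the clock (median -0.26, adjusted p = 0.582), goblet (0.122, adjusted p = 0.113) and Wnt (0.114, adjusted p = 0.106) calls, the filter at the median gene ended the MHC class II (adjusted p = 0.0994) and Wnt (adjusted p = 0.0553) calls, and centring on the median ended the adipocyte call (adjusted p = 0.0502).

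DHX9-837 alone against control gave 1457 genes up and 1161 down. S100g fell by 4.26 (SE 0.25, adjusted p = 3.89e-05), and Mptx1 by 3.68 (SE 0.51, adjusted p = 0.00223). Trpv6 (-3.46, SE 0.28), Gsdmc2 (-2.90, SE 0.31) and Saa1 (-2.68, SE 0.12) fell as well. Sycn (-2.61), Gsdmc3 (-2.49), Cyp4f15 (-2.33), Ces2a (-2.30), Pck1 (-1.56), Apol10a (-1.50) and Ndufb2 (-1.50) were also among the 12 largest falls. Akr1b8 rose most (2.03, SE 0.18, adjusted p = 0.000314), then Plet1 (1.76), Cldn8 (1.68), Asns (1.65), Pnpla1 (1.65) and Slc7a11 (1.62). Sprr1a, Lpcat4, Aqp4, Ms4a12, Ereg and the annexin gene Anxa1 rose by 1.34 to 1.56. None of the 25 named genes lost its call in an alternative that tested it. The filter at the median gene and the removal of tied genes can leave a gene untested. Single genes were not followed with all probe sets as features or at the 1.5-fold limit. Without DHX9-837 replicate 3, 942 genes rose. With arrays centred on their median 1265 rose and 1480 fell, so the balance turned over. The DHX9-837 means of Mptx1 (5.03) and Cyp4f15 (4.77) and the control mean of Slc7a11 lay under the level filter of 5.28, so the size and rank of their folds are uncertain.

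Camera called 13 lists with DHX9-837. Cell cycle genes had 21 of 32 up (26 adjusted over the list alone, median 0.36, adjusted p = 1.1e-11, or adjusted p = 0.332 with an estimated correlation). In ribosome biogenesis 15 of 25 rose (16 adjusted over the list alone), with Nop2 (0.64) and Gnl3 (0.73); the median was 0.23 (adjusted p = 3.91e-09, or adjusted p = 0.332 with an estimated correlation). B and plasma cells had 5 of 19 up (13 adjusted over the list alone, median 0.45, adjusted p = 2.12e-05, or adjusted p = 0.581 with an estimated correlation). Fibroblasts and matrix had 6 of 19 up (7 adjusted over the list alone, median 0.16, or 0.251 without control replicate 2, adjusted p = 0.000541, or adjusted p = 0.461 with an estimated correlation). Macrophages had 5 of 17 up and 1 down (the same adjusted over the list alone, median 0.17, adjusted p = 0.00492, or adjusted p = 0.332 with an estimated correlation). The macrophage median was 0.0989 without control replicate 3, 0.0999 without DHX9-837 replicate 3 and 0.507 without tied genes. Endothelium had 4 of 18 up (5 adjusted over the list alone, median 0.10, or 0.163 without tied genes, adjusted p = 0.00564, or adjusted p = 0.332 with an estimated correlation). Stress response genes had 8 of 23 up (9 up and 1 down adjusted over the list alone), led by Shmt2 (1.00), Asns and Mthfd2 (1.24). Their median was 0.10 (adjusted p = 0.013, or adjusted p = 0.332 with an estimated correlation). MHC class II had 3 of 10 up (6 adjusted over the list alone, median 0.23, adjusted p = 0.0134, or adjusted p = 0.658 with an estimated correlation). Wnt targets and crypt genes had 5 of 21 up, Myc (0.72) included, and 1 down (6 and 2 adjusted over the list alone, median 0.13, adjusted p = 0.0191, or adjusted p = 0.345 with an estimated correlation).

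Downward with DHX9-837, absorptive colonocytes had 8 of 24 down and 2 up (11 and 2 adjusted over the list alone), with Slc37a2 (-1.39) and Slc26a3 (-0.63) down and the uroguanylin gene Guca2b (1.22) up. The median was -0.13 (adjusted p = 0.00776, or adjusted p = 0.332 with an estimated correlation). Interferon response genes had 6 of 29 down and 0 up (10 down adjusted over the list alone), with Gbp2 (-0.74), Oasl2 (-0.41), Dhx58 (-0.55) and Zbp1 (-0.73). Their median was -0.17 (adjusted p = 0.0127, or adjusted p = 0.804 with an estimated correlation), and the call ended without control replicate 3 (adjusted p = 0.07) and without DHX9-837 replicate 2 (median -0.105, adjusted p = 0.0884). Clock genes had 7 of 16 down and 3 up (9 and 4 adjusted over the list alone, median -0.30, adjusted p = 0.0134, or adjusted p = 0.332 with an estimated correlation). Smooth muscle had 0 of 20 called by limma (0 adjusted over the list alone, median -0.13, adjusted p = 0.0134, or adjusted p = 0.804 with an estimated correlation). Its call ended without control replicate 2 (median -0.0826, adjusted p = 0.205) and without DHX9-837 replicate 3 (adjusted p = 0.0696). Without DHX9-837 replicate 1 (adjusted p = 0.0747) or replicate 3 (adjusted p = 0.0549) the MHC class II call ended, and without replicate 3 the Wnt call (adjusted p = 0.0696). Leaving out genes with identical values in 2 or more arrays ended the clock (median -0.173, adjusted p = 0.652), absorptive (-0.121, adjusted p = 0.107) and Wnt (0.145, adjusted p = 0.107) calls, and the filter at the median gene ended the MHC class II call (adjusted p = 0.0509).

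The log2 folds of the hairpins correlated at r = 0.689 across the 16808 genes, which are not independent replicates. Both contrasts use the same 3 controls, and simulated unchanged groups gave r = 0.499. The covariance was 0.0349 against a simulated 0.00614, a difference of 0.0287, and 77.7% of genes had the same sign against 66.7%. The hairpins called 631 genes alike, 395 up and 236 down, and 2 in opposite directions. Independent lists, which leave out the shared controls, would share 59.5. Simulations without an effect shared 0.01, which is low in advance, since few genes are called where none changed. Neither value gives how many real calls would coincide through the shared controls. The excess over these values can in part come from the shared controls, which are too few to divide. Of the 631 genes, 455 changed more with DHX9-837, with a median absolute log2 fold of 0.461 against 0.364. The shared count was 293 without control replicate 1, 244, 179 and 118 without DHX9-1271 replicates 1, 2 and 3, and 419 without DHX9-837 replicate 2.

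**Figure D3:**
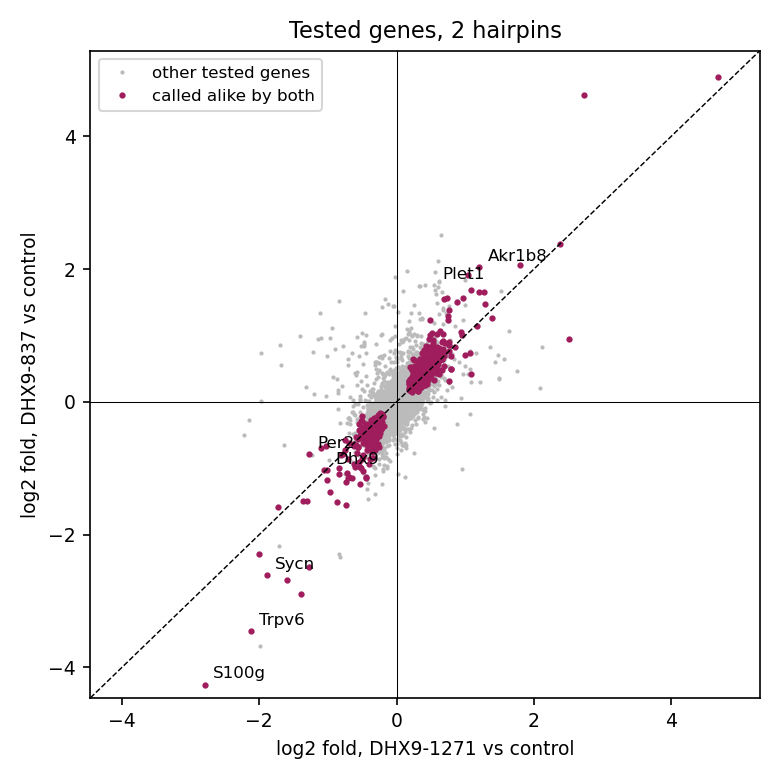
Log2 fold against control of each of the 16808 tested genes with DHX9-1271 (x axis) and DHX9-837 (y axis); the dashed line marks equal folds. The 631 genes called alike by both hairpins are magenta, and S100g, Trpv6 and Sycn lie at the lower left, below the dashed line.

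Compared directly, DHX9-837 had 117 genes higher and 203 lower than DHX9-1271, although Dhx9 itself did not pass the test. The adipocyte-associated genes Car3 (log2 difference 1.70, SE 0.22, adjusted p = 0.0122), Retn (1.04) and Fabp4 (0.88) were higher in DHX9-837, as were Plet1 (1.22, SE 0.14, adjusted p = 0.00908), Guca2b (1.04), Slc7a11 (1.04), Akr1c18 (0.86) and Lpcat4 (0.86). Gsdmc2 (-1.52), Cyp4f15 (-1.51), S100g (-1.47, SE 0.25, adjusted p = 0.0263), Gsdmc3 (-1.22), Ly6g6c (-1.21), Saa1 (-1.09, SE 0.12, adjusted p = 0.00583), Slc37a2 (-1.07, SE 0.079, adjusted p = 0.00194) and Adamts18 (-1.04) were lower. The size of the Cyp4f15 difference is uncertain, since its DHX9-837 mean (4.77) lay under the level filter. Of the 16 genes named beside Dhx9, 14 lost their call in at least 1 fit that left out an array. Counts up and down were 74 and 128 without control replicate 3. They were 18 and 37, 33 and 38, and 9 and 19 without DHX9-1271 replicates 1, 2 and 3. They were 25 and 33, 36 and 85, and 39 and 95 without DHX9-837 replicates 1, 2 and 3.

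Of the 11 lists called in this difference, the interferon response list had the smallest camera p. All 29 members had a negative log2 difference, 2 of them past the test, Oasl2 (-0.52, SE 0.090) and Oas2 (-0.65, SE 0.13), and 17 fell adjusted over the list alone. The median was -0.34 (adjusted p = 1.54e-14, or adjusted p = 0.317 with an estimated correlation), and fry did not call the list (adjusted p = 0.0622). The list's mean per array was 8.25 to 8.54 in controls, 8.57 to 8.70 in DHX9-1271 and 8.10 to 8.44 in DHX9-837. Smooth muscle had 1 of 20 lower, Synm (-0.34), and 8 adjusted over the list alone (median -0.19, adjusted p = 8.83e-07, or adjusted p = 0.49 with an estimated correlation). Goblet cells had 1 of 20 lower, Klk1 (-0.35), and 3 adjusted over the list alone (median -0.11, or -0.167 without tied genes, adjusted p = 0.0176, or adjusted p = 0.745 with an estimated correlation). Ribosome biogenesis had 3 of 25 higher, Nop2 (0.40), Nop56 (0.41) and Npm1 (0.41), and 12 adjusted over the list alone (median 0.16, adjusted p = 1.71e-09, or adjusted p = 0.202 with an estimated correlation). Adipocytes had 4 of 11 higher and 1 lower (7 and 1 adjusted over the list alone, median 0.30, or 0.462 both without tied genes and with no level filter, adjusted p = 2.18e-05, or adjusted p = 0.317 with an estimated correlation). Small intestine had 0 of 18 called by limma (0 adjusted over the list alone, median 0.75, adjusted p = 4.08e-05, or adjusted p = 0.565 with an estimated correlation), with list means per array of 7.54, 6.67 and 7.40 in DHX9-1271 and 8.45, 7.004 and 9.24 in DHX9-837. The small intestine median was 0.483 without DHX9-1271 replicate 2, and 1.14 and 0.369 without DHX9-837 replicates 2 and 3. Immediate early and heat shock genes had 2 of 23 higher and 1 lower (7 and 1 adjusted over the list alone, median 0.11, or 0.167 without tied genes, adjusted p = 0.000181, or adjusted p = 0.317 with an estimated correlation). Stress response had Shmt2 (0.52) higher of 23 (6 adjusted over the list alone, median 0.073, adjusted p = 0.000312, or adjusted p = 0.269 with an estimated correlation). Of 22 p53 targets Ccng1 (0.49) and Tnfrsf10b (0.36) were higher (7 adjusted over the list alone, median 0.059, adjusted p = 0.00578, or adjusted p = 0.202 with an estimated correlation). The p53 median was 0.0357 without DHX9-1271 replicate 3 and 0.0181 without DHX9-837 replicate 1. Cell cycle had 0 of 32 called by limma (0 adjusted over the list alone, median 0.040, adjusted p = 0.0223, or adjusted p = 0.773 with an estimated correlation), and the call ended without DHX9-1271 replicate 2 (adjusted p = 0.1) and without DHX9-837 replicate 3 (median 0.0223, adjusted p = 0.327). Macrophages had 0 of 17 called by limma (1 higher and 1 lower adjusted over the list alone, median 0.11, adjusted p = 0.024, or adjusted p = 0.32 with an estimated correlation). That call ended without DHX9-1271 replicate 3 (median 0.0594, adjusted p = 0.0714) and without DHX9-837 replicate 3 (median 0.0573, adjusted p = 0.207), and the median was 0.206 without tied genes.

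**Figure D4:**
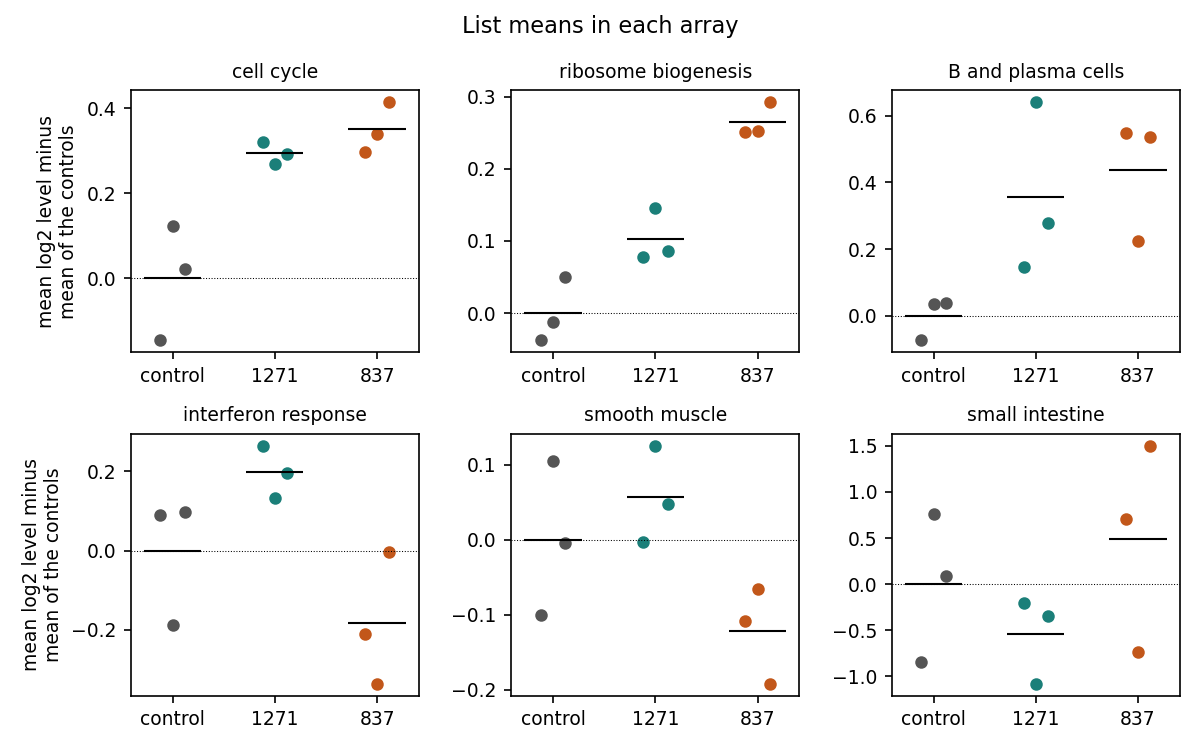
Mean log2 level of 6 gene lists in each array, minus the mean of the control arrays; points are arrays and lines are group means, and each panel has its own y axis. All 6 knockdown arrays lie above the controls for the cell cycle list, and the small intestine list spreads widely within groups.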

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

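The tests of immune cell lists, of the general epithelium list, of the clock arms and of other splits of the arrays were chosen after the results they bear on had been seen at least in part; the B cell covariate was added after the data were seen, though written down before its own result, as were the tests that leave out single arrays.

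The interferon response list differed between the hairpins by a median of -0.34 (DHX9-837 minus DHX9-1271). The camera call stayed in 9 of 9 fits that left out an array, which argues against a single array, but with an estimated correlation it was lost (adjusted p = 0.317). Fry did not call the list in this difference either (adjusted p = 0.0622). Fewer macrophages or B cells are argued against by their lists' medians in this difference (0.106 and 0.053, at 0.0573 to 0.127 and -0.0339 to 0.181 over fits that left out an array), and more T and NK cells in DHX9-1271 by a median of -0.034 against control, where interferon genes had 0.196 (at -0.117 to 0.00347 and 0.11 to 0.258 over such fits; p = 2e-05, 3e-05 and 0.00498 in 100000 permutations). These permutations moved genes between the lists, and genes are not independent replicates, so they do not measure spread between arrays. Fewer T and NK cells in DHX9-837 stay open: against control their median was -0.149 (adjusted p = 0.0561) and that of interferon genes -0.172. Without DHX9-837 replicate 2 these were -0.0885 (adjusted p = 0.257) and -0.105. Without control replicate 2 they were -0.231 (adjusted p = 0.0288) and -0.201. The means of both lists correlated at 0.879 within groups. Between the hairpins the T and NK difference was -0.054 (adjusted p = 0.161), or -0.118 (adjusted p = 0.0137) without DHX9-837 replicate 3. It was -0.00409 (adjusted p = 0.979) without DHX9-837 replicate 2 and -0.0201 (adjusted p = 0.488) without DHX9-1271 replicate 2. Control arrays alone spanned 8.25 to 8.54 in the interferon list mean, so variation between samples stays open, as does the hairpin line, the difference the design names, which was not tested apart from these.

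Clock genes differed between knockdown and control in both hairpins. Leaving out single arrays kept the camera call in 9 of 9 fits, but an estimated correlation ended it (adjusted p = 0.254), as did leaving out genes with identical values in 2 or more arrays (adjusted p = 0.639), with a median of -0.305 there against -0.323. Repressor-phase genes (Per1, Per2, Per3, Dbp, Tef, Hlf, Nr1d1, Nr1d2, Ciart, Bhlhe41) had a median of -0.40 and activator-phase genes (Arntl, Npas2, Clock, Nfil3, Cry1) one of 0.14, a difference of -0.542 (exact permutation p = 0.037). That permutation moved genes between the arms, and genes are not independent replicates, so its p does not measure spread between arrays. A difference in the time of tissue collection, which the labels do not give, could part the arms in this way. However, Nr1d1 went against its arm. Only 4 of the 16 clock genes had a positive log2 fold, Nr1d1 among them, so not all activator-phase genes rose. The arms were fixed after Per2 had been seen. Time of collection and reduced Dhx9, the difference the design names, both stay open and were not tested apart.

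The cell cycle list was higher with both hairpins, and the call stayed in 9 of 9 fits that left out an array, but not with an estimated correlation (adjusted p = 0.362). With the B cell list mean as a covariate, 97.5% of the cell cycle median was kept (0.333 before, 0.325 after, adjusted p = 4.39e-12 by camera with the preset correlation), while antigen receptor genes moved from a median of 0.149 to -0.035. Only 1 cell cycle gene was then called, with a median SE of 0.112 against 0.0746 and 5 residual degrees of freedom against 6, whose shares in the lost calls were not tested apart. Less muscle wall as the whole cause would raise epithelial genes by about as much, but the general epithelium median was 0.00638 (SD of members 0.202, permutation p = 0.0001 against the cell cycle list), and smooth muscle genes had medians of 0.0547 in DHX9-1271 (adjusted p = 0.167, or 0.00867 without control replicate 2 and 0.0293 without DHX9-1271 replicate 1) and -0.126 in DHX9-837 (adjusted p = 0.0134, or 0.205 without control replicate 2 and 0.0696 without DHX9-837 replicate 3), so less muscle in DHX9-837 stays open as a part. The permutation against the cell cycle list moved genes, which are not independent replicates, so it does not measure spread between arrays. Cycling cells outside the lists named here stay open. Reduced Dhx9, the difference the design names, stays open too and was not tested apart from these explanations.

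The count of genes called in both hairpins against control was set beside counts from other splits of the arrays, which cannot exclude chance. Of 100 of the 840 splits of the 9 arrays into 3 groups of 3, 1 gave as many as the real 2263. The highest other split gave 1301, and it kept the 3 control arrays together while mixing the hairpins, so its log2 folds were the real ones. Splits that mix groups carry the differences between groups into the spread within groups, which lowers their counts. Low counts there are therefore no measure of chance alone. For the contrasts of 3 arrays against 3, 10 splits are too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many. The real and highest other counts were 741 and 0 for DHX9-1271, 2618 and 1 for DHX9-837, and 320 and 0 for the difference.

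Other lists differed between the hairpins by a test of the difference itself, given as median DHX9-837 minus DHX9-1271: cell cycle 0.0399, p53 targets 0.0593, stress response 0.0734, ribosome biogenesis 0.161, goblet cells -0.106, smooth muscle -0.187, adipocytes 0.298, macrophages and granulocytes 0.106, small intestine 0.754, and immediate early and heat shock genes 0.111. With an estimated correlation their adjusted p was 0.202 to 0.773. The cell cycle call also ended without DHX9-1271 replicate 2 (adjusted p = 0.1) and DHX9-837 replicate 3 (median 0.0223, adjusted p = 0.327), and the macrophage call without DHX9-1271 replicate 3 (median 0.0594, adjusted p = 0.0714) and DHX9-837 replicate 3 (median 0.0573, adjusted p = 0.207). The p53 median was 0.0357 without DHX9-1271 replicate 3 and 0.0181 without DHX9-837 replicate 1. The small intestine median was 0.483 without DHX9-1271 replicate 2, and 1.14 and 0.369 without DHX9-837 replicates 2 and 3. Without tied genes the medians were -0.167 for goblet cells, 0.462 for adipocytes, 0.206 for macrophages and 0.167 for immediate early and heat shock genes. Named genes that differed between the hairpins by the same test and were higher in DHX9-837 were Car3 (1.70), Plet1 (1.21), Guca2b (1.04), Retn (1.04), Slc7a11 (1.04), Fabp4 (0.88), Akr1c18 (0.863), Lpcat4 (0.86), Sprr1a (0.589), Per2 (0.486) and Pnpla1 (0.37). Those lower in DHX9-837 were Gsdmc2 (-1.52), Cyp4f15 (-1.51), S100g (-1.47), Gsdmc3 (-1.22), Ly6g6c (-1.21), Saa1 (-1.09), Slc37a2 (-1.07), Adamts18 (-1.04), Pck1 (-0.819), Sycn (-0.717), Klf12 (-0.665) and Apol10a (-0.637). Of the 958 probe sets that the probe table does not name, which the comparisons leave out, 29 were called higher and 30 lower in both hairpins against control.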

How the results depend on the processing

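The fits without genes that have identical values in 2 or more arrays, and with the B cell list as a covariate, were chosen after the data were seen. Counts of genes that moved over 1.5 times are given below; the causes were not tested except where fewer arrays or more features show them. Dhx9 stayed called in both hairpins and each of them, with log2 folds over the fits that left out an array of -1.05 to -0.982 (both), -1.04 to -0.972 (DHX9-1271) and -1.06 to -0.993 (DHX9-837), and -0.0421 to 0.00214 for the difference. No called list or named gene turned its direction in the alternatives run.

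Genes up and down in DHX9-1271 against control were 254 and 154 with no filter, 255 and 152 with all probe sets as features, 207 and 129 with only the arrays compared and 72 and 46 at a 1.5-fold limit, and 719 rose with trend and robust moderation. In DHX9-837 they were 942 and 732 with only the arrays compared and 241 and 159 at 1.5-fold, and in both hairpins 146 and 80 at 1.5-fold. In the difference they were 53 and 87 with no filter, 55 and 89 with all probe sets, 197 and 357 with trend and robust moderation, 282 and 437 with array weights and 44 and 44 at 1.5-fold; 180 rose with cyclic loess and 320 fell with the filter at the median gene. Genes called alike numbered 342 with no filter, 339 with all probe sets, 280 with only the arrays compared and 85 at 1.5-fold.

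Leaving out single arrays gave 77 to 431 up and 51 to 283 down for DHX9-1271, 942 to 1333 and 775 to 1183 for DHX9-837, 779 to 1161 and 584 to 910 for both, 9 to 125 and 19 to 237 for the difference, 118 to 623 called alike, and a correlation of hairpins from 0.61 to 0.747. Lists called ranged over 12 to 16, 11 to 15, 10 to 13 and 10 to 14 in that order. With an estimated correlation camera called 0 lists in each comparison, and fry called 3 in the difference.

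No pairing of the samples by replicate number was detected: deviations of same-numbered arrays correlated at -0.37 to 0.26, 2 of 9 over 0.1, and 2 arrays correlated best with their own number. So few arrays cannot exclude a pairing. With the number as a replicate block, 264 genes rose and 143 fell in DHX9-1271, 62 and 106 in the difference, and 351 were called alike; 11 calls of named genes, in DHX9-1271 and the difference, ended with unchanged log2 folds, as did the adipocyte call in DHX9-1271 (adjusted p = 0.053), and T and NK cells gained one in DHX9-837 (adjusted p = 0.033). Genes with identical values in 2 or more arrays (7619) were called less often than others in both hairpins, 5.47% against 20.1%, and leaving them out ended 8 list calls. Over the settings other than leaving out an array, named genes kept their call in 834 fits and lost it in 29, and lists tested by camera with the preset correlation kept their side of the threshold in 1126, lost a call in 14 and gained one in 13. Apart from these, an estimated correlation ended 50 list calls of 50, and fry did not make 21 of them and made 7 others. Without tied genes the medians of 13 called lists moved over 1.5 times, 12 away from 0 and 1 (clock, DHX9-837) towards it. Since tied genes were called less often, leaving them out selects genes that vary between these arrays. The larger medians given without tied genes are therefore no independent estimates of effect size. With arrays centred, the DHX9-1271 medians of ribosome biogenesis (0.0552) and Wnt targets (0.0501) were lower, and still called. Averaging the probe sets of a gene changed no list call or call of a named gene, but only 4 probe sets duplicated a symbol, so it could change little. Signal over background was not used here.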

Other observations

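The gene families below were chosen after the data were seen, by a scan of all 484 families of at least 5 tested genes that share the letters of their symbol, tested in each direction by Fisher's exact test with Benjamini-Hochberg adjustment over 968 tests. In both hairpins against control, 7 of 12 Ces genes (carboxylesterases, which hydrolyse esters of drugs and lipids) fell, 58.3% against 5.37% of other genes (adjusted p = 0.000811). Ces2a (-2.15), Ces2b (-0.96), Ces1d (-0.92) and Ces2e (-0.76) fell most. Of the 12 tested symbols that share the letters Hoxb, the name of a cluster of patterning genes, 6 fell (adjusted p = 0.00843). The family was formed by these letters alone, so not every member need be a patterning gene. Hoxb3, Hoxb4, Hoxb5, Hoxb6, Hoxb7 and Hoxb8 fell by 0.25 to 0.47 on the log2 scale, while Hoxb9 had a log2 fold of -0.14 (adjusted p = 0.135). The labels do not name the segment of large intestine, and neither the segment nor the locus of the transgene was tested against this fall. Annexin genes had 6 of 11 up (adjusted p = 0.0292), with Anxa1 (1.03) and Anxa3 (0.62) highest. Butyrophilin-like genes had 4 of 6 down (adjusted p = 0.0292), Btnl6 (-0.88), Btnl2 (-0.79), Btnl1 (-0.67) and Btnl4 (-0.44). Members of a family are not independent, and paralogs can share probes.

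The immunoglobulin heavy-chain genes Ighg2b and Ighg2c were chosen after their values were seen. Ighg2b had log2 levels of 8.79 ± 0.23 in control, 9.82 ± 0.52 in DHX9-1271 and 10.7 ± 0.13 in DHX9-837 (SD, n = 3 each), and rose by 1.47 in both hairpins (adjusted p = 0.0024). Ighg2c rose by 1.42 (adjusted p = 0.0204). Such genes have near-identical copies, so their single values are uncertain.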
